A study of Jatropha curcas with 22 samples.

How the data were processed

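Gene expression was measured by RNA sequencing in young leaves and root tips of Jatropha curcas, a drought-tolerant oilseed shrub, in seedlings of a strain from the Cape Verde islands. Per the labels, seedlings were 36 days old at the start, water was withheld for up to 49 days, and libraries came from pools of 6 plants (days 0 and 49) or 3 plants (days 13 and 52), with the number not given for the joint day 49/52 controls. The protocol in the labels gives 7 days of rewatering, while the rewatered samples are labelled day 52, 3 days after the last day without water. Libraries were made from 400 ng of total RNA with the TruSeq RNA v2 kit, which keeps no strand information, and sequenced as single-end reads of 50 bp on an Illumina HiSeq instrument. The aligner, the counting program, the genome build and the treatment of reads that match several genes are not given in the sources used here.

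The authors provided a table of read counts per gene model, whole numbers with no normalization, for 57437 gene models. The deposited RPKM table (reads scaled to gene length and library size) holds the same libraries, and its values carry 1 decimal. Its lowest value is 1.0, held by all cells with a count of 0, as adding 1 would give, and its sorted columns differ by at most 0.7, as quantile normalisation would give. Neither step is given in the sources used here. The authors' gene descriptions gave names to 25568 gene models, 15648 had no description, and 6147 had no read in any library. No coordinates came with the gene models, and the reference gene table at hand uses other identifiers, so positions are not given.

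Libraries were grouped by organ, treatment and day as the labels state, into 11 groups of 2 libraries. The day 49 and day 52 controls carry a joint label, so they form 1 group of 2 libraries that serves as the control of both severe drought and rewatering. Whether the 2 libraries of a group come from separate plants is not given in the sources used here, so p-values measure only the spread between these libraries. Libraries with the same replicate number in different groups did not pair: the correlation of their deviations from the group means ran from -0.422 to 0.308 in leaf and from -0.327 to 0.21 in root.

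Total counts ran from 37104762 to 82215677 reads per library. At these totals, 3 reads correspond to well under 1 CPM (count scaled to library size), and the spread between the libraries of a group exceeded counting error in all 11 groups, with a chi-square per degree of freedom of 11.3 to 145.2. Reads carry no molecular identifiers, so limits drawn from counts cover counting error only. Where both libraries of a group had 0 reads, the fold was computed against a floor of 3 reads per library and is written as a bound. Where a group had 1 to 3 reads in all, levels and reads are given without a fold, and medians of lists were also computed with genes at 0 set to their bound.

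The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups of the fit, scaled by TMM, and fitted with a robust quasi-likelihood model of group means, with 1 fit over the 12 leaf libraries (23200 genes), 1 over the 10 root libraries (24924 genes) and 1 over all 22 (25939 genes) for comparisons across organs. Each contrast was tested by the two-sided quasi-likelihood F test, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the F statistic. Levels are CPM over TMM-scaled totals, given as mean ± SD over the 2 libraries of a group. The common dispersion was 0.0362 in leaf and 0.076 in root. The pipeline was tested on simulated data: in simulated copies of the leaf moderate comparison edgeR called 32% of genes changed by a factor of 2 and 77% of those changed by a factor of 4, and in copies of the root moderate comparison 5% and 55%.

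A set of 34 gene lists (stress proteins, hormones, photosynthesis, growth, cell wall and barrier layers, transport, transcription factor families and markers of other cell types), written as patterns on gene descriptions, held 1615 genes. The patterns were adapted to the spelling of the deposited descriptions before any comparison was run. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move, on balance, one way. Leaf-enriched and root-enriched genes were defined at an adjusted p under 0.01 and at least 8-fold between the organs, in the controls not used by the comparison under test. The covariance and correlation that a shared control gives to severe drought and rewatering came from 10 simulations of unchanged groups against a simulated control. Shared calls of such groups are near 0 by construction and were not used.

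Named genes followed a rule: per main comparison, the 5 largest rises and 5 largest falls among changed genes with a mean log2 CPM of at least 3, groups without overlap in CPM and an informative description, and from each list the tested member with the smallest p. In the other comparisons the largest rise and the largest fall were taken. The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

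Alternatives were median-ratio (RLE) size factors in edgeR, DESeq2 1.42.0, no low-count filter and a stricter filter (mean log2 CPM of at least 2). Limma used log2 of the deposited RPKM minus 1, then plus 1 or plus 0.1, also unfiltered. Others were a single fit over all libraries, replicate as a block, leaving each library out, 4-fold organ sets and other list tests. A comparison of severe drought and rewatering, and of their organ differences, against the day 13 controls and the list patterns as first spelled were added after seeing the data. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. A second accession named in the series design and mapping of the reads to a genome were not analysed here.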

Results

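RNA was sequenced from young leaves and root tips of Jatropha curcas seedlings that were kept watered, left without water or watered again. The series holds 22 libraries, 12 from leaf and 10 from root, in 11 groups of 2. Each organ was sampled under moderate drought (13 days without water) with its day 13 control, under severe drought (49 days) and after rewatering (day 52). A further control carries a joint label of days 49 and 52. Leaf was also sampled at day 0, before water was withheld. Total counts ran from 37104762 to 82215677 reads per library. The rewatered leaf libraries were both the deepest (replicate 1) and the shallowest (replicate 2). Leaf libraries had reads on 27394 to 29099 gene models, and the day 49/52 root controls on 40952 and 38267, more than any other library. All levels are CPM (counts scaled to library size), mean ± SD with n = 2 libraries per group, and errors of log2 fold changes are SE. Where a list is followed by a median and a pair of adjusted p, the first p is from camera at the preset correlation and the second is the adjusted p with an estimated correlation.

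Severely droughted libraries stood apart from all others in both organs. The first principal component of log2 CPM held 68.1% of the variance in leaf and 54.7% in root, and on it the severe libraries lay far from the rest. In root the second component (25.1%) ran from the day 13 controls and a rewatered library at -59.44 to -53.33, through the other rewatered library and moderate drought, to the day 49/52 controls at 77.79 and 95.89. The root controls of the earlier and later days were thus placed at opposite ends of this axis. Libraries of a group correlated across genes with r from 0.973 in the day 13 root controls to 0.998 in rewatered leaf.

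**Figure D1:**
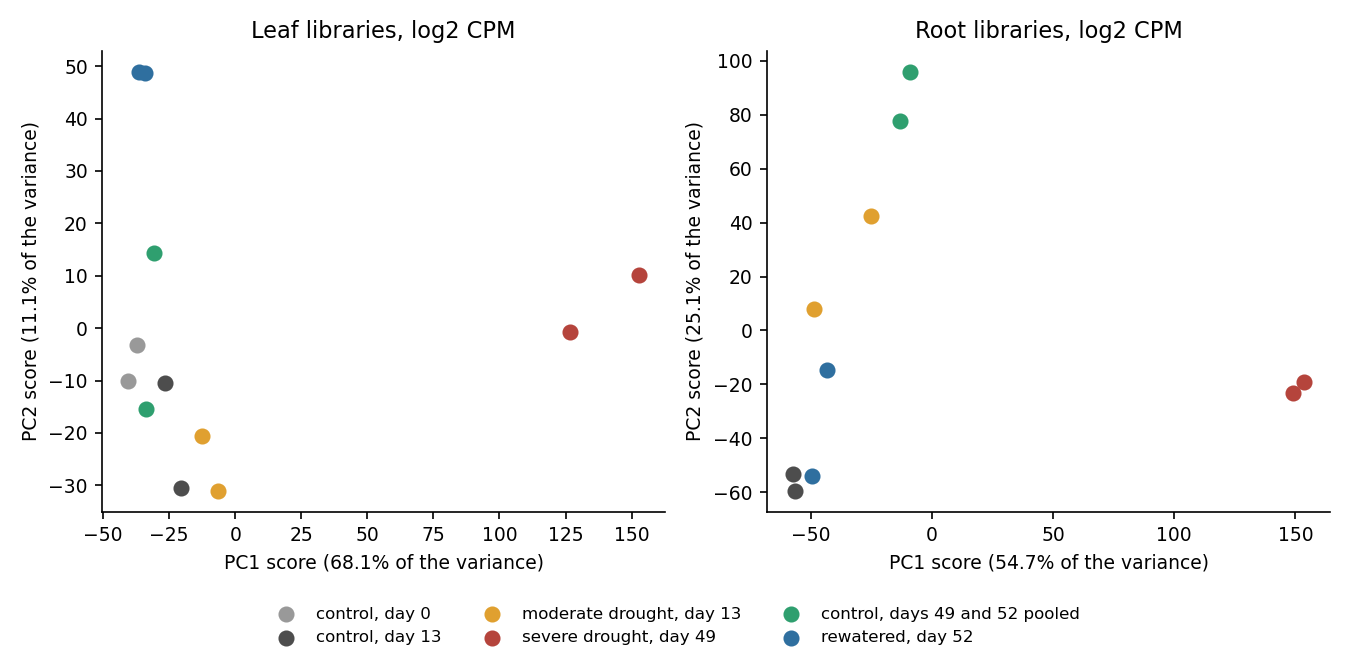
Scores of each library on the first 2 principal components of log2 CPM, leaf libraries in the left panel and root libraries in the right, 1 point per library coloured by group. Severe drought lies apart on the first component in both organs, and the day 13 and day 49/52 root controls lie at opposite ends of the second.

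**Figure D2:**
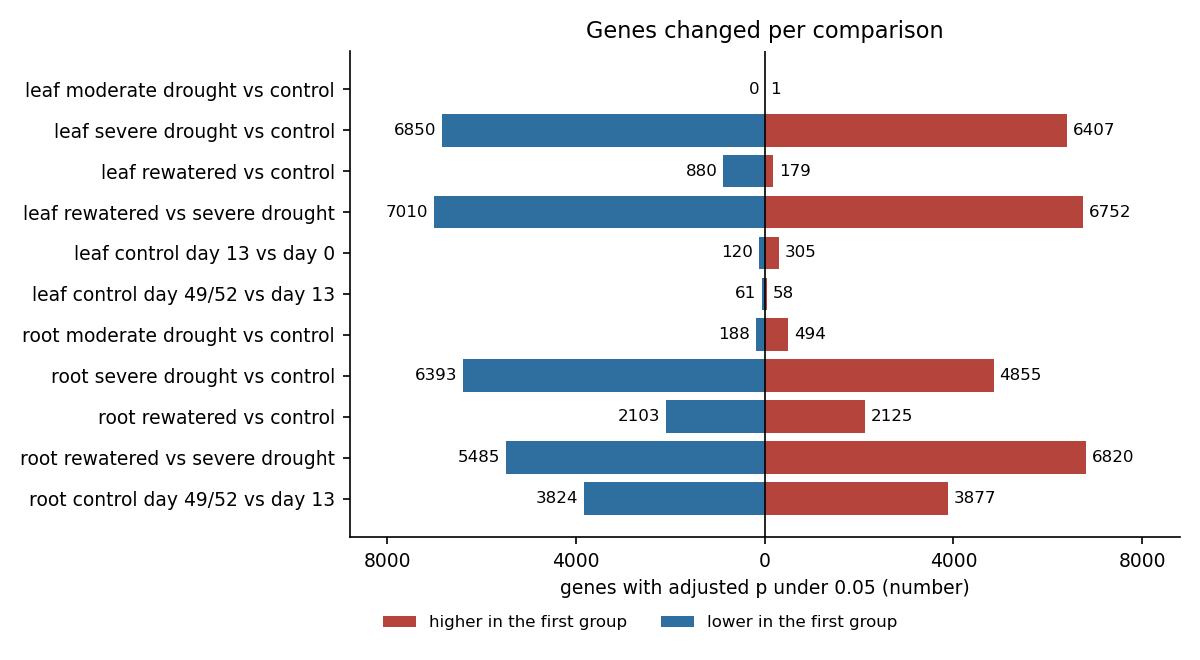
Number of genes with an edgeR adjusted p under 0.05 in each comparison within an organ, bars to the right for genes higher in the first group named and to the left for lower ones. Severe drought changed 13257 genes in leaf and 11248 in root, and moderate drought 1 and 682.

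The first question was what moderate drought changes in leaf. A single gene passed the test, Jcr4S16138.20, described as a hypothetical protein and named here after its values were seen: it had 4.83 and 3.69 CPM under moderate drought and 0.771 and 0.878 in the control (log2 2.37, SE 0.22, adjusted p = 0.0105). Late embryogenesis abundant (LEA) proteins and dehydrins, hydrophilic proteins that accumulate in drying tissue, were the only list that camera called above the other genes. Over all genes 0 of its 16 tested members were called by edgeR, and 6 were higher adjusted over the list alone, with a median log2 fold change of 0.41 (camera adjusted p = 2.2e-06, and adjusted p = 0.065 with an estimated correlation). Its member with the smallest p, the LEA gene Jcr4S05404.40, had a log2 fold change of 2.28 (SE 0.42, adjusted p = 0.17). A highly ABA-induced protein phosphatase 2C, Jcr4S07634.50, a negative regulator of abscisic acid (ABA) signalling, had 1.27 (adjusted p = 0.23).

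Small shifts below the other genes were found in leaf under moderate drought for cytosolic ribosomal proteins (median -0.25, camera adjusted p = 9.8e-10, and adjusted p = 0.71 with an estimated correlation) and cell division genes (-0.21, 2.6e-06, and adjusted p = 0.36 with an estimated correlation). Organelle-encoded genes had a median of -0.56 (adjusted p = 0.00044, and adjusted p = 0.71 with an estimated correlation), heat shock proteins -0.26 (0.0029, and 0.71) and class III peroxidases -0.17 (0.013, and 0.37). Without replicate 2 of the day 13 leaf control the camera calls of these 3 lists ended (adjusted p = 0.077, 0.088 and 0.095, with the heat shock median at 0.35), and without replicate 1 of moderate leaf those of organelle genes (0.063) and peroxidases (0.23) and without its replicate 2 that of heat shock genes (0.056). With the stricter filter the peroxidase median was 0.04 (adjusted p = 0.69). The edgeR test found 1 of 23200 genes at an adjusted p under 0.05 and 2007 at an unadjusted p under 0.05, DESeq2 found 280, and limma on RPKM 0. The count was 19 or 51 without replicate 1 or 2 of the control and 4 without either moderate library.

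Severe drought in leaf was compared with the day 49/52 control to ask how young leaves respond when water has been withheld to the end of the treatment. Ferritin (Jcr4S03468.40), the iron storage protein, rose 426-fold to 240 ± 115 from 0.567 ± 0.229 (log2 8.73, SE 0.80, adjusted p = 2e-05). A homeobox leucine zipper gene (Jcr4S06344.30) rose 914-fold to 64.4 ± 49.6, a gene described as stress-responsive (Jcr4S01474.40) 309-fold to 490 ± 155, and a xyloglucan endotransglucosylase (Jcr4S02117.30), an enzyme that remodels cell wall polymers, 292-fold to 86.9 ± 10.2. The STS14 protein gene Jcr4S10843.10 had the largest rise (1660-fold, log2 10.7, SE 2.02, adjusted p = 0.0029), with libraries far apart (98.5 ± 131). A PHD finger gene (Jcr4S13152.30) fell 396-fold to 0.1 ± 0.0113 from 40.9 ± 7.89, a galactose oxidase gene (Jcr4S00108.10) 322-fold, a germin-like gene (Jcr4S00461.10) 311-fold and a ubiquitin hydrolase gene (Jcr4S05419.30) 263-fold. In all 13257 of 23200 genes changed, 6407 higher and 6850 lower.

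Genes of cell division, which encode cyclins, histones and the replication machinery, were the most strongly lowered list in severely droughted leaf. Of its 97 tested members 75 fell and 6 rose, the same numbers as adjusted over the list alone, and the median log2 fold change was -2.48 (camera adjusted p = 5.7e-44, and adjusted p = 0.0053 with an estimated correlation). Histone H2A 11 (Jcr4S00074.150) fell 225-fold to 0.997 ± 0.0606 from 224 ± 11.3 (log2 -7.81, SE 0.19, adjusted p = 2.3e-09). This was the only list in severe leaf that camera also called with an estimated correlation. Cell wall loosening genes fell in 46 and rose in 8 of 90 (median -0.90, adjusted p = 6.2e-07, and adjusted p = 0.097 with an estimated correlation). Among the secondary wall and lignin genes 23 of 40 fell and 4 rose (median -1.35, 0.00058, and adjusted p = 0.27 with an estimated correlation), with fasciclin-like arabinogalactan protein 2 (Jcr4S12978.20) down 16.3-fold to 18.5 ± 2.38 from 301 ± 55.6. Aquaporins, the water channels, fell in 20 and rose in 2 of 29 (median -1.19, 6e-04, and adjusted p = 0.48 with an estimated correlation), with NIP1.1 (Jcr4S00197.140) down 7.84-fold to 4.3 ± 0.0349 from 33.7 ± 4.75. Of 147 ribosomal protein genes 98 fell and 5 rose (104 and 5 adjusted over the list alone; median -0.74, 0.00011, and adjusted p = 0.83 with an estimated correlation). Against the day 13 control, a comparison added after seeing the data, the ribosomal median was -0.38 and the call ended (adjusted p = 0.11).

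Most genes of the synthesis and breakdown of abscisic acid, the hormone that closes stomata in drying plants, rose in severely droughted leaf. Of 6 ABA synthesis genes 4 rose and 0 fell (median 2.50, camera adjusted p = 0.044, and adjusted p = 0.28 with an estimated correlation), led by a gene described as zeaxanthin chloroplastic-like (Jcr4S00215.20) at 23.1-fold, 47 ± 8.84 from 2.04 ± 0.413 (log2 4.53, SE 0.23, adjusted p = 1e-07). All 4 ABA breakdown genes rose, with an ABA 8'-hydroxylase (Jcr4S05715.10) 2.56-fold higher, and of 4 ABA signalling genes 1 rose, the ABA-induced phosphatase 2C Jcr4S07634.50, 15.7-fold to 471 ± 40.2. DREB and ERF transcription factors rose in 9 and fell in 1 of 14 (median 2.04, adjusted p = 0.044, and adjusted p = 0.27 with an estimated correlation), with ERF3 (Jcr4S00982.160) 11-fold higher at 120 ± 17.8. Among LEA and dehydrin genes 7 of 16 rose and 4 fell (8 and 4 adjusted over the list alone), with an LEA gene (Jcr4S00616.50) 43.7-fold higher at 1100 ± 347 from 25.3 ± 4.72. The camera call was absent for LEA genes (adjusted p = 0.069) and for ABA breakdown (0.13), and those for ABA synthesis and for DREB and ERF factors ended without either day 49/52 control library (adjusted p = 0.081 without replicate 1 and 0.083 without replicate 2 in both lists) and with the stricter filter (0.055 and 0.17). The ABA synthesis median was 0.47 on the RPKM plus 1 (adjusted p = 0.10), 1.29 on the RPKM plus 0.1 (0.088) and 1.67 against the day 13 control, a comparison added after seeing the data (0.12). With that control LEA and dehydrin genes (0.80, 0.0069, and adjusted p = 0.12 with an estimated correlation) and DREB and ERF factors (2.89, 0.0077, and 0.12) were called at the preset correlation. The DREB and ERF median was 0.45 without a filter (adjusted p = 0.21), 0.52 with the stricter filter, 0.58 in a single fit over all libraries (0.084) and 0.10 on the RPKM plus 1 without a filter (0.15). Adjusted over the list alone, 24 of the 34 lists in severe leaf had the same numbers of changed genes and none differed by more than 6.

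Camera called none of the other lists in severely droughted leaf. Enzymes that make osmolytes, which lower the osmotic potential of cells, rose in 11 and fell in 4 of 24, with a galactinol-sucrose galactosyltransferase (Jcr4S00009.110), an enzyme of raffinose synthesis, 5.01-fold higher. Genes of sugar cleavage and starch breakdown rose in 23 and fell in 10 of 42, and those of sugar transport in 5 and 9 of 26. Photosystem and antenna genes rose in 5 and fell in 16 of 49, carbon fixation genes in 4 and 0 of 11, chlorophyll synthesis genes in 2 and 4 of 14, chlorophyll breakdown genes in 7 and 3 of 11 and senescence genes in 10 and 9 of 24.

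Transcription factor and hormone lists of severe leaf were among those without a camera call, apart from the DREB and ERF and ABA synthesis lists above. NAC factors rose in 27 and fell in 14 of 71, WRKY factors in 19 and 10 of 52 and HD-ZIP factors in 4 and 6 of 16. Auxin response genes rose in 15 and fell in 30 of 74, with an auxin-induced 5NG4-like gene (Jcr4S03936.10) 134-fold lower, and gibberellin metabolism genes in 7 and 8 of 32, with a gibberellin 3-beta-hydroxylase (Jcr4S00062.140) 28.9-fold lower. Antioxidant enzymes rose in 8 and fell in 13 of 37, glutathione transferases in 14 and 7 of 31, heat shock proteins in 20 and 17 of 70 and class III peroxidases in 8 and 21 of 49. Among cuticle and wax genes 14 of 43 rose and 14 fell, with a GDSL esterase lipase (Jcr4S02681.20) 44.2-fold higher. Suberin genes rose in 3 and fell in 6 of 11, guard cell genes in 3 and 1 of 7, nitrate and ammonium uptake genes in 7 and 7 of 24, root hair genes in 2 and 1 of 3 and organelle-encoded genes in 2 and 0 of 14. Curcin genes, which encode the ribosome-inactivating proteins of this plant, rose in 2 and fell in 1 of 4. The curcin precursor Jcr4S01069.20 was 2.96-fold higher (log2 1.57, SE 0.28, adjusted p = 0.00087), and against the day 13 control (added after seeing the data) its log2 fold change was 0.47 (adjusted p = 0.18).

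Rewatered leaf was compared with the day 49/52 control to ask how far expression had returned, and with severe drought to ask what rewatering changed. Against severe drought 13762 genes changed, 6752 higher and 7010 lower, and against the control 1059, 179 higher and 880 lower. Against severe drought a gibberellin-regulated protein gene (Jcr4S05849.30) rose 447-fold to 56.1 ± 6.83, and cell division genes rose in 77 and fell in 5 of 97 (median 2.45, camera adjusted p = 9.2e-44, and adjusted p = 0.013 with an estimated correlation). Against the control, a cytochrome P450 (Jcr4S00155.50) fell 20.6-fold to 1.33 ± 0.0604 from 27.3 ± 0.135 (log2 -4.36, SE 0.23, adjusted p = 2.1e-05). An alpha-amylase subtilisin inhibitor (Jcr4S01589.10) fell 15.9-fold, a glucosyltransferase (Jcr4S02337.50) 14.2-fold, lipoxygenase LOX2 (Jcr4S01832.30), of the jasmonate pathway, 13.9-fold, and a calcium/proton exchanger (Jcr4S00152.110) 24.4-fold to 5.47 ± 1.26 from 132 ± 44.4. The largest rises were those of a shikimate dehydrogenase (Jcr4S05584.50, 5.28-fold), a geraniol 8-hydroxylase-like gene (Jcr4S10051.20, 5.14-fold), an alpha-dioxygenase (Jcr4S01218.10, 4.36-fold), a stachyose synthase (Jcr4S01910.40, 3.4-fold) and a lipid-transfer protein gene (Jcr4S00065.140, 2.85-fold).

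Several lists were below the control in rewatered leaf. Aquaporins fell in 7 and rose in 0 of 29 (11 and 0 adjusted over the list alone; median -0.48, camera adjusted p = 1e-05, and adjusted p = 0.34 with an estimated correlation), and NIP1.1 (Jcr4S00197.140) was again low at 7.25-fold below the control. Class III peroxidases fell in 7 of 49 (17 adjusted over the list alone, with 1 higher; median -0.48, 1e-05, and adjusted p = 0.086 with an estimated correlation). Photosystem genes fell in 2 of 49, and in 20 adjusted over the list alone (median -0.63, 5.1e-07, and adjusted p = 0.46 with an estimated correlation). Cuticle and wax genes fell in 7 of 43 (12 adjusted over the list alone, with 1 higher; median -0.51), chlorophyll breakdown genes in 3 of 11 (-0.67) and curcin genes in 3 of 4 (-1.65), with the curcin precursor Jcr4S01069.20 at 27.3 ± 3.68 against 82.3 ± 33.3. For these 3 lists the adjusted p was 7.3e-05, 6.5e-05 and 5e-05 by camera, and the adjusted p = 0.24, 0.26 and 0.23 with an estimated correlation.

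Gibberellin metabolism genes of rewatered leaf fell in 6 of 32 (median -0.44, camera adjusted p = 0.0068, and adjusted p = 0.26 with an estimated correlation), with a gibberellin 20-oxidase 1-like gene (Jcr4S04169.10) down 12.9-fold. WRKY factors fell in 6 of 52 (-0.44, 0.0029, and adjusted p = 0.44 with an estimated correlation), glutathione transferases in 5 of 31 (-0.32, 0.0017, and 0.47), senescence genes in 3 of 24 (-0.33, 0.019, and 0.44), nitrate genes in 3 of 24 (-0.51, 0.021, and 0.23) and wall loosening genes in 3 of 90 (-0.35, 0.021, and 0.34). Above the other genes were sugar cleavage and starch genes (1 of 42 higher, 8 adjusted over the list alone; median 0.24, 0.00018, and adjusted p = 0.086 with an estimated correlation) and ribosomal protein genes (1 of 147 higher; 0.22, 3.4e-06, and 0.59). Of the named genes, the cytochrome P450 Jcr4S00155.50, Jcr4S01589.10, Jcr4S02337.50, NIP1.1, the gibberellin oxidase and peroxidase 52 (Jcr4S00925.60, 10.2-fold lower) kept their calls in every setting run. All 5 of the largest rises lost theirs without replicate 2 of either rewatered leaf or the control. Camera calls ended for wall loosening, ribosomal, nitrate and WRKY genes without replicate 1 of the control (adjusted p = 0.33, 0.20, 0.32 and 0.13), for glutathione transferases and senescence genes without its replicate 2 (0.14 and 0.11), and for gibberellin genes on the RPKM plus 1 (median -0.04, 0.14). With the day 13 leaf control (added after seeing the data) calls ended for sugar cleavage and starch genes (median 0, adjusted p = 0.76), cuticle and wax genes (-0.25, 0.14), wall loosening (-0.14, 0.37), nitrate (-0.28, 0.20) and senescence genes (-0.25, 0.29). Calls were gained for antioxidant enzymes (-0.37, 0.0086, and adjusted p = 0.60 with an estimated correlation) and organelle-encoded genes (-0.60, 0.033, and 0.65). The ribosomal median was 0.62 (4.7e-25, and adjusted p = 0.60 with an estimated correlation), that of chlorophyll breakdown -1.03 (4e-11, and 0.13) and that of aquaporins -0.25 (0.01, and 0.60). The count of changed genes was 97 or 53 without replicate 1 or 2 of rewatered leaf, and 4582 or 248 without replicate 1 or 2 of the control, and DESeq2 called 2748.

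The leaf controls were compared with each other to see what changed in watered leaves between the sampling days, where age, date and, for days 0 and 13, the number of plants per pool differ together. From day 0 to day 13, 305 genes rose and 120 fell. The clock gene FKF1 (Jcr4S03391.30), a blue light receptor, had the largest rise, 27.8-fold with libraries at 85.3 ± 68.9, and a zinc finger gene (Jcr4S07158.20) the largest fall, 4.52-fold. Ribosomal protein genes fell in 23 of 147 and in 120 adjusted over the list alone (median -0.76, camera adjusted p = 2.3e-57, and adjusted p = 0.38 with an estimated correlation). From day 13 to days 49/52, 58 genes rose and 61 fell, among them a xyloglucan endotransglucosylase 33 precursor (Jcr4S01936.90, 4.95-fold higher) and an ornithine decarboxylase-like gene (Jcr4S04145.10, 4.62-fold lower). The first count was 23 or 2 without replicate 1 or 2 of day 0 and 216 without replicate 2 of day 13. The later count was 820 or 2 without replicate 1 or 2 of the later control and 27 without replicate 2 of day 13.

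**Figure D3:**
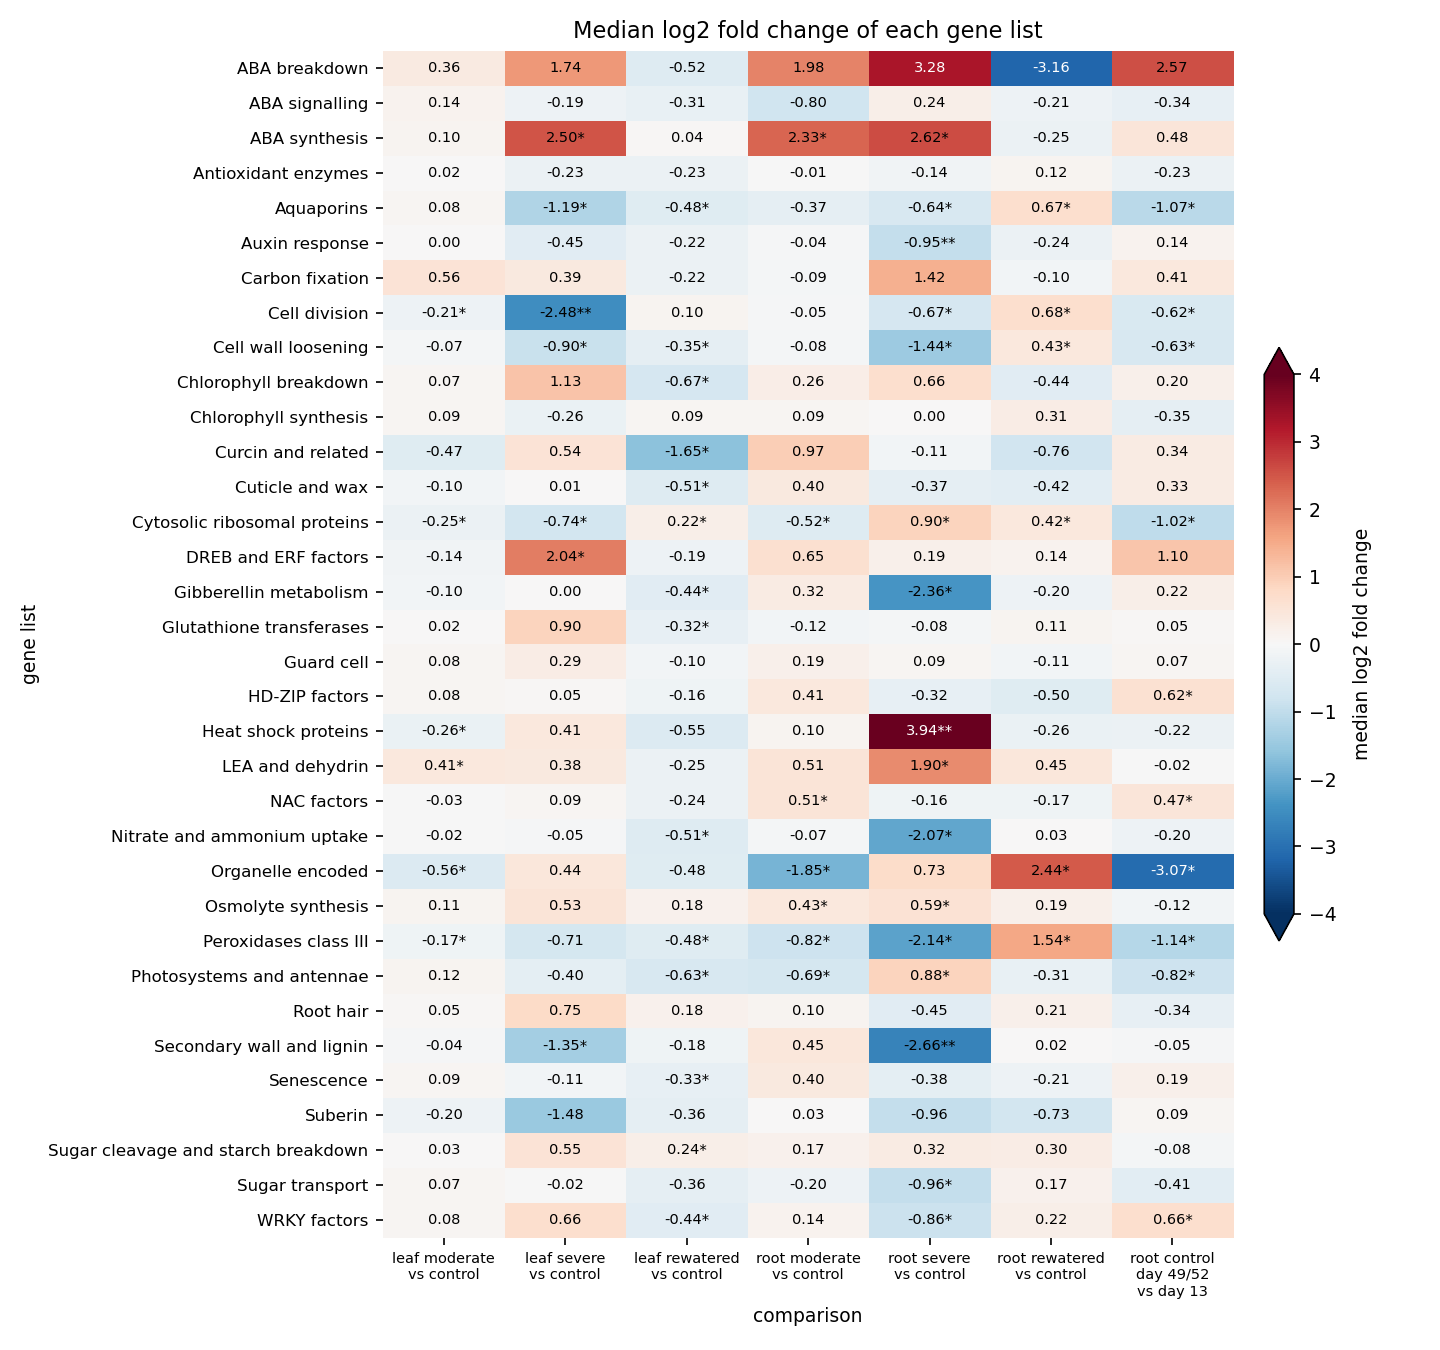
Median log2 fold change of each gene list (lines of the grid) in each of 7 comparisons (columns), red for higher and blue for lower in the first group, with 1 asterisk for a camera adjusted p under 0.05 at the preset correlation and a pair of asterisks where it also passed with an estimated correlation. Cell division in severe leaf (-2.48) and heat shock (3.94), auxin response (-0.95) and secondary wall (-2.66) in severe root carry a pair.

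Moderate drought in root was compared with the day 13 root control to ask how roots respond to the first weeks without water. A 9-cis-epoxycarotenoid dioxygenase, NCED5 (Jcr4S15630.10), which catalyses the committed step of ABA synthesis, rose 13.9-fold to 136 ± 37.8 from 9.78 ± 0.456 (log2 3.80, SE 0.30, adjusted p = 0.011). An ABA 8'-hydroxylase 4 (Jcr4S01285.10) rose 15.8-fold, and the ABA receptor PYL4-like (Jcr4S01692.40) fell 4.94-fold to 19.7 ± 5.07 from 97.3 ± 30. A dehydrin (Jcr4S01519.40) rose 2.93-fold to 2120 ± 412 and the water channel NIP1-2-like (Jcr4S07404.30) 4.25-fold. The largest rises were those of an EG45-like gene (Jcr4S00216.20, 316-fold), cysteine proteases (Jcr4S00250.10, 222-fold, and Jcr4S06821.10, 82.3-fold), a UDP-glucosyl transferase (Jcr4S01054.10, 100-fold) and a glycine-rich protein gene (Jcr4S06018.30, 71.6-fold). The largest falls were those of a lipid binding protein gene (Jcr4S00971.120, 487-fold, from libraries far apart at 1350 ± 1350), a stearoyl-ACP desaturase (Jcr4S03522.10, 28.2-fold), a polyketide cyclase (Jcr4S00137.160, 21.7-fold), a heme oxygenase (Jcr4S06729.30, 17.9-fold) and a gene described as desacetoxyvindoline 4- (Jcr4S06388.10, 14.9-fold).

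Among the lists in moderately droughted root, ABA synthesis rose in 2 of 6 members, and in 5 adjusted over the list alone (median 2.33, camera adjusted p = 3.5e-08, and adjusted p = 0.17 with an estimated correlation). Class III peroxidases, which cross-link cell walls, fell in 8 of 70 and in 20 adjusted over the list alone (median -0.82, 5.8e-10, and adjusted p = 0.62 with an estimated correlation), with cationic peroxidase 2 (Jcr4S07131.10) down 4.2-fold. NAC factors were above the other genes (2 of 80 higher; median 0.51, 0.00023, and adjusted p = 0.62 with an estimated correlation), as were osmolyte genes (0 of 23 called; 0.43, 0.028, and 0.64). Below the other genes were ribosomal protein genes (1 of 145 higher, 0 lower; median -0.52, 3.1e-11, and adjusted p = 0.64 with an estimated correlation), photosystem genes (-0.69, 2e-04, and 0.64) and organelle-encoded genes (-1.85, 0.02, and 0.67). Wall loosening genes rose in 5 and fell in 5 of 122, 14 and 18 adjusted over the list alone, with beta-expansin 3 (Jcr4S08184.10) 46.2-fold higher. The organelle call ended without replicate 2 of the day 13 root control (-0.26, adjusted p = 0.88) or of moderate root (0.051), and the osmolyte call without replicate 1 of either (0.20 and 0.068). In all 682 of 24924 genes changed, 494 higher and 188 lower. The excess of rises was smaller with DESeq2 (1721 higher and 1427 lower) and in a single fit over all libraries (1509 and 1315), and absent without replicate 1 of the control (2149 and 2230). The count was 2 without replicate 2 of the control, 4379 without its replicate 1, and 19 or 1078 without replicate 1 or 2 of moderate drought. Each gene named above lost its call without that replicate 2, and DESeq2 called 3148 genes.

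Severe drought in root was compared with the day 49/52 root control. Heat shock proteins, chaperones that bind unfolded proteins, made up all 5 of the largest rises. The small heat shock gene Jcr4S02800.20 rose 2300-fold to 169 ± 25.6 from 0.0738 ± 0.0521 (log2 11.17, SE 1.29, adjusted p = 0.00055), Jcr4S01511.10 rose 1750-fold to 992 ± 113 and Jcr4S07181.10 1540-fold to 932 ± 151. Jcr4S00560.70 and Jcr4S03340.10 rose 1430-fold and 1420-fold. Of 74 tested heat shock genes 48 rose and 7 fell, 50 and 8 adjusted over the list alone (median 3.94, or 3.10 with genes at 0 set to their bound; camera adjusted p = 2.4e-30, and adjusted p = 0.014 with an estimated correlation). The list was also called with the day 13 control, a comparison added after seeing the data (4.48, 1.2e-21, and adjusted p = 0.011 with an estimated correlation). Small heat shock genes rose in 23 of 32 and those of 70 kDa in 5 of 15. The share of all reads on heat shock genes was 4.93% and 5.18% in severe roots and at most 1.58% in any other library. In all 11248 of 24924 genes changed, 4855 higher and 6393 lower.

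Most called members of the secondary wall, auxin response, gibberellin and nitrate uptake lists fell in severely droughted root. Secondary wall and lignin genes fell in 36 and rose in 1 of 49 (median -2.66, -2.45 with bounds; camera adjusted p = 3.6e-12, and adjusted p = 0.035 with an estimated correlation), with a caffeic acid 3-O-methyltransferase-like gene (Jcr4S06671.20), of lignin synthesis, down 57.5-fold to 0.46 ± 0.219. Auxin response genes fell in 36 and rose in 3 of 83 (median -0.95, -0.73 with bounds; 7.4e-05, and adjusted p = 0.035 with an estimated correlation), with the auxin-induced gene Jcr4S03936.10 down 42.4-fold to 1.45 ± 0.105 from 61.7 ± 2.28. Gibberellin metabolism genes fell in 25 and rose in 2 of 36 (median -2.36, 2.3e-12, and adjusted p = 0.094 with an estimated correlation), with gibberellin 20-oxidase Jcr4S01656.20 down 139-fold to 0.672 ± 0.0458 from 93.9 ± 6.02. Nitrate and ammonium uptake genes fell in 19 and rose in 3 of 34 (-2.07, 4.6e-06, and adjusted p = 0.094 with an estimated correlation), with a nitrate transporter (Jcr4S04372.30) down 20.2-fold to 1.04 ± 0.0505 from 21.2 ± 0.87. Class III peroxidases fell in 41 and rose in 2 of 70 (-2.14, 3.4e-10, and adjusted p = 0.24 with an estimated correlation), with cationic peroxidase 2 (Jcr4S07131.10) down 19.7-fold. Wall loosening genes fell in 56 and rose in 10 of 122 (-1.44, 0.0014, and adjusted p = 0.18 with an estimated correlation), although the xyloglucan endotransglucosylase Jcr4S02117.30 rose 33.8-fold. With the day 13 control (added after seeing the data) secondary wall genes (-3.12, 4.4e-08) and auxin response genes (-1.45, 0.0012) kept their calls at the preset correlation and lost them with an estimated correlation (adjusted p = 0.096 in both). The peroxidase median was -3.84 (1.1e-17, and adjusted p = 0.13 with an estimated correlation).

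Cell division genes of severe root fell in 48 and rose in 6 of 94 (median -0.67, camera adjusted p = 0.00042, and adjusted p = 0.53 with an estimated correlation), with a kinesin (Jcr4S00326.10) down 8.08-fold. Aquaporins fell in 14 and rose in 5 of 31 (-0.64, 0.0078, and adjusted p = 0.53 with an estimated correlation). NIP1-2-like Jcr4S07404.30 fell 147-fold, and NIP1-1-like Jcr4S10731.10 had 2 and 1 reads (0.0363 ± 0.0182) against 53 ± 23.2 in the control. Sugar transport genes fell in 17 and rose in 3 of 28 (-0.96, 0.0077, and adjusted p = 0.38 with an estimated correlation), with the hexose carrier HEX6 (Jcr4S00441.10) down 30.3-fold. WRKY factors fell in 23 and rose in 3 of 61 (-0.86, 0.002, and adjusted p = 0.46 with an estimated correlation). Among other large falls, a cytochrome P450 (Jcr4S00208.180) had 1 read in severe roots (0.0123 ± 0.0174) against 30.9 ± 5.18, mavicyanin (Jcr4S05635.20) fell 1560-fold and kiwellin (Jcr4S01193.80) 1430-fold. The gene Jcr4S06388.10, with 0 reads in severe roots, was at least 57.4-fold lower. The day 13 control (added after seeing the data) gave medians of -2.56 for aquaporins (adjusted p = 8.4e-08, and 0.20 with an estimated correlation), -1.50 for cell division (1.4e-08, and 0.26) and -1.17 for sugar transport (0.0078, and 0.26). ABA breakdown (5.15, 0.033, and adjusted p = 0.19 with an estimated correlation) and HD-ZIP factors (1.06, 0.017, and 0.19) were called with this control at the preset correlation. With this control kiwellin was at -0.51 (adjusted p = 0.90) and mavicyanin at -6.38 (0.072). The mavicyanin call also ended without replicate 1 or 2 of severe root (adjusted p = 0.10 and 0.096).

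Most called members of the LEA, ABA synthesis and osmolyte lists rose in severely droughted root. LEA and dehydrin genes rose in 10 and fell in 1 of 19 (median 1.90, camera adjusted p = 0.00092, and adjusted p = 0.13 with an estimated correlation), with Jcr4S05404.40 up 139-fold to 74.1 ± 24.6 from 0.526 ± 0.118. ABA synthesis genes rose in 4 and fell in 2 of 6 (2.62, 0.015, and adjusted p = 0.24 with an estimated correlation), with Jcr4S00215.20 up 8.69-fold. The ABA 8'-hydroxylase Jcr4S05715.10 rose 85.5-fold to 8.73 ± 2.26 and the phosphatase 2C Jcr4S07634.50 26.1-fold to 739 ± 88.8, while ABA breakdown genes rose in 3 and fell in 1 of 6 and ABA signalling genes in 2 and 1 of 5, without a camera call. Osmolyte genes rose in 9 and fell in 2 of 23 (0.59, 0.0017, and adjusted p = 0.44 with an estimated correlation), with the galactosyltransferase Jcr4S00009.110 up 13.1-fold to 791 ± 107. Ascorbate peroxidase Jcr4S00717.110 rose 46-fold to 307 ± 8.05 from 6.68 ± 0.976. Ribosomal protein genes rose in 98 and fell in 3 of 145, 107 and 3 adjusted over the list alone (0.90, 9.8e-13, and adjusted p = 0.53 with an estimated correlation), and photosystem genes rose in 15 and fell in 2 of 41 (0.88, 0.0045, and 0.57). Against the day 13 root control the ribosomal median was -0.10 (adjusted p = 0.91), the photosystem median 0.16 (0.58) and the WRKY median -0.25 (0.45). The ABA synthesis call ended on the RPKM plus 1 (adjusted p = 0.31), the photosystem call with the stricter filter (0.15) and the aquaporin call without a filter (0.058).

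In severe root camera called none of the other lists. Adjusted over the list alone, 17 of the 34 lists had the same numbers and none differed by more than 9. Antioxidant enzymes rose in 11 and fell in 7 of 36, glutathione transferases in 5 and 5 of 27, with Jcr4S08266.70 350-fold lower at 0.311 ± 0.0577, and sugar cleavage and starch genes in 16 and 10 of 43. NAC factors rose in 20 and fell in 24 of 80, HD-ZIP factors in 4 and 2 of 16 and DREB and ERF factors in 3 and 4 of 19. Cuticle and wax genes rose in 9 and fell in 14 of 43, suberin genes in 2 and 3 of 9, and senescence genes in 5 and 6 of 26. Root hair genes rose in 2 and fell in 2 of 5, guard cell genes in 1 and 2 of 7, curcin genes in 0 and 1 of 4 and organelle-encoded genes in 1 and 0 of 14. Carbon fixation genes rose in 4 and fell in 1 of 7, chlorophyll synthesis genes in 3 and 2 of 14 and chlorophyll breakdown genes in 3 and 2 of 10. The number of changed genes in severe root was 7473 or 7446 without replicate 1 or 2 of severe drought and 6926 or 6781 without replicate 1 or 2 of the control. On the RPKM plus 1 the percent of changed genes that were higher was 57.2 in place of 43.2.

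**Figure D4:**
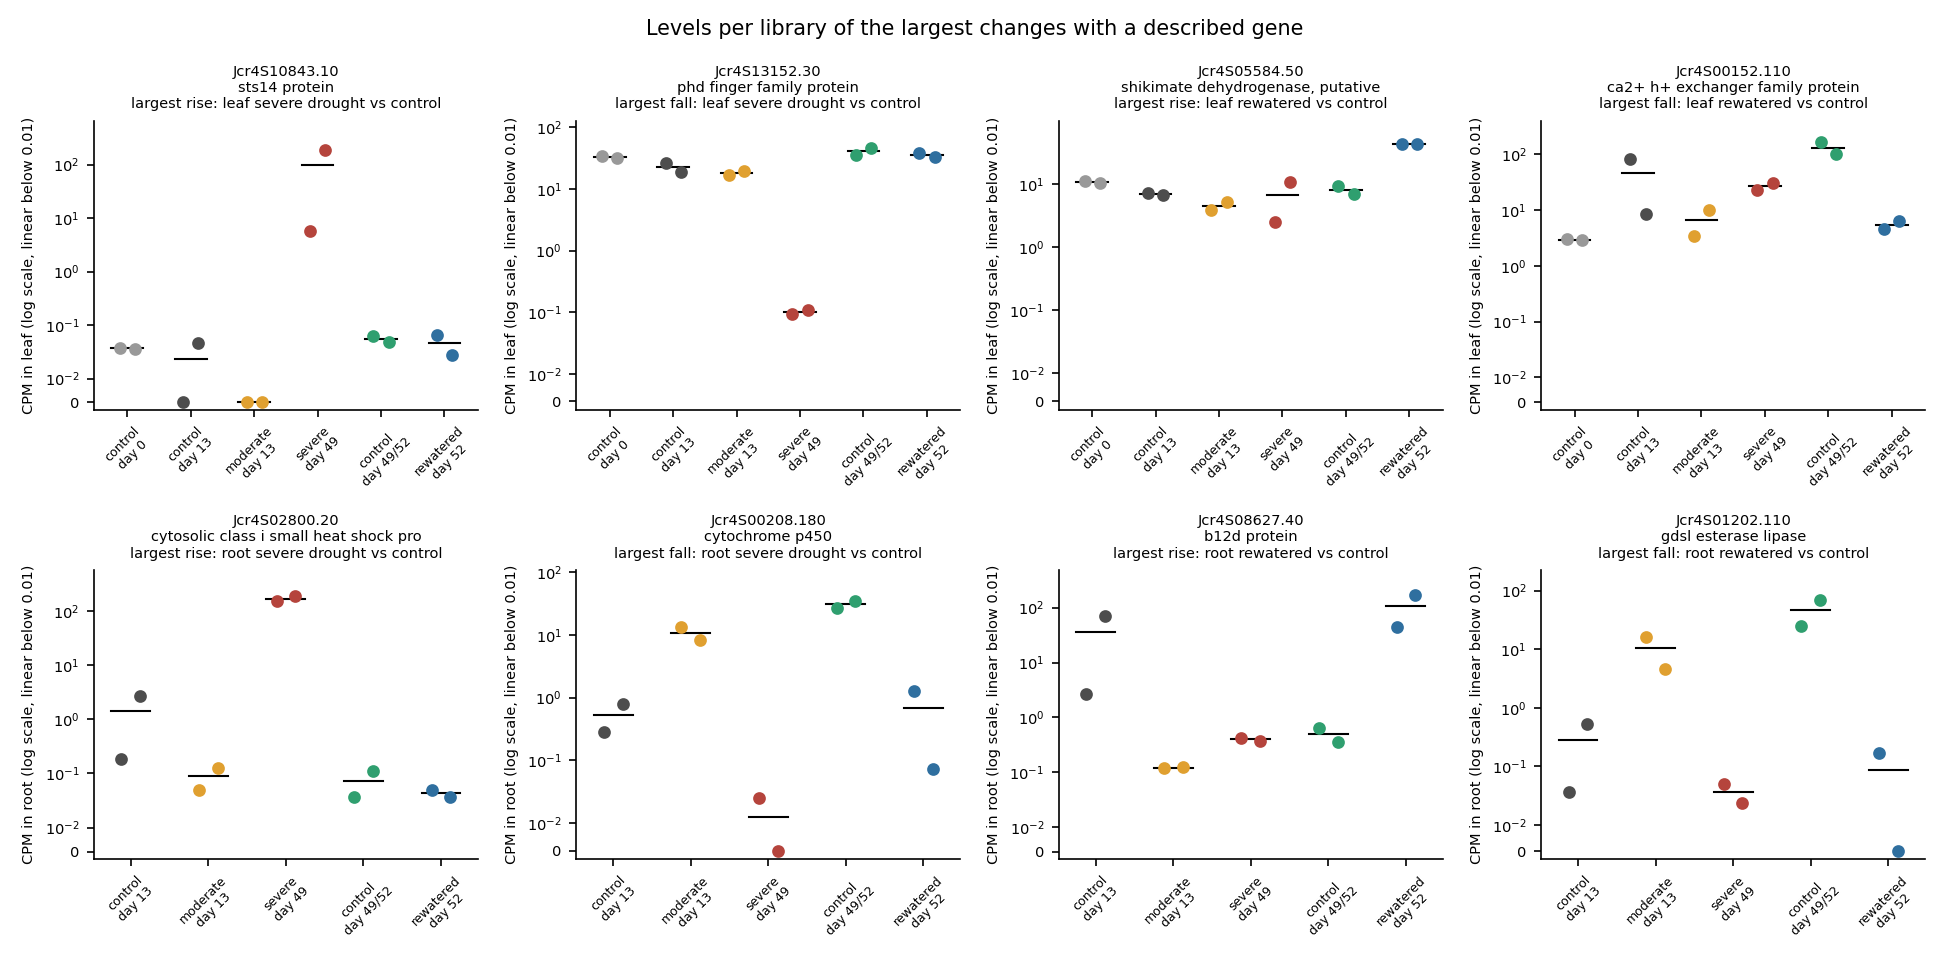
CPM per library (points, log scale above 0.01 and linear below) and group means (lines) of the largest rise and the largest fall in severe drought and rewatering against control, leaf in the upper panels and root in the lower ones. The small heat shock gene Jcr4S02800.20 had 169 ± 25.6 CPM in severe roots and 0.0738 ± 0.0521 in their control.

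Rewatered root was compared with severe drought and with the day 49/52 control. Against severe drought 12305 genes changed, 6820 higher and 5485 lower, while limma on the RPKM plus 1 called 5654 higher and 7625 lower. Heat shock genes fell in 53 and rose in 9 of 74 (median -4.91, camera adjusted p = 5e-27, and adjusted p = 0.03 with an estimated correlation), with Jcr4S02800.20 3800-fold lower at 0.0427 ± 0.00875. Class III peroxidases rose in 57 and fell in 3 of 70 (3.72, 3.8e-19, and adjusted p = 0.11 with an estimated correlation), nitrate genes in 19 and 3 of 34 (2.37, 2e-05, and 0.065), secondary wall genes in 32 and 5 of 49 (2.04, 1.7e-08, and 0.065) and aquaporins in 20 and 4 of 31 (2.13, 4.1e-05, and 0.27).

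Against the day 49/52 control, rewatered root differed in 4228 genes, 2125 higher and 2103 lower. A B12D gene (Jcr4S08627.40) was 209-fold higher at 106 ± 88.2, the lipid binding gene Jcr4S00971.120 85-fold higher at 536 ± 291, a non-symbiotic hemoglobin (Jcr4S02362.60) 61.6-fold higher, glutathione transferase tau 19 (Jcr4S07700.10) 47-fold higher and early nodulin 93 (Jcr4S01309.10) 45.2-fold higher. A GDSL lipase (Jcr4S01202.110) was 600-fold lower, fasciclin-like genes (Jcr4S06525.30, Jcr4S06525.40 and Jcr4S01772.30) 183-fold, 170-fold and 115-fold lower, and an acyl-ACP thioesterase (Jcr4S02908.30) 107-fold lower. Class III peroxidases were higher in 30 and lower in 2 of 70 (35 and 3 adjusted over the list alone; median 1.54, camera adjusted p = 1.7e-13, and adjusted p = 0.50 with an estimated correlation). Cell division genes were higher in 36 and lower in 6 of 94 (50 and 9 adjusted over the list alone; 0.68, 1.1e-06, and adjusted p = 0.74 with an estimated correlation), wall loosening genes in 33 and 9 of 122 (0.43, 0.0014, and 0.50), aquaporins in 10 and 3 of 31 (0.67, 0.0043, and 0.74) and ribosomal protein genes in 11 and 2 of 145 (0.42, 1.5e-06, and 0.82). Organelle-encoded genes had a median of 2.44 (0.029, and 0.82 with an estimated correlation), and 0.22 without replicate 1 of rewatered root (adjusted p = 0.88). Without replicate 1 of the control the aquaporin and organelle calls ended (adjusted p = 0.059 and 0.11). The aquaporin call also ended on the RPKM plus 1, plus 0.1 and plus 1 without a filter (medians 0.35, 0.50 and 0.15; adjusted p = 0.17, 0.15 and 0.094). The organelle call ended with the stricter filter (0.20) and on the RPKM plus 1 (0.068, and 0.083 without a filter).

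These differences depended on the control. Against the day 13 root control (added after seeing the data) edgeR called 10 genes in rewatered root, 6 higher and 4 lower, and the list medians were 0.03 for peroxidases (camera adjusted p = 0.95), 0.06 for cell division (1) and -0.13 for wall loosening (1). Aquaporins (-0.55, camera adjusted p = 2.5e-06) and ribosomal proteins (-0.56, 2.6e-18) were called in the opposite direction, and photosystem genes (-0.95, 6.5e-10), WRKY factors (0.59, 3e-08), sugar cleavage and starch genes (0.30, 0.01) and heat shock proteins (-0.27, 0.028) were called as well. None of these 6 calls held with an estimated correlation (adjusted p = 0.65, 0.81, 0.65, 0.65, 0.65 and 0.73 in the order given). Ferredoxin-nitrite reductase (Jcr4S01372.10), an enzyme of nitrate assimilation, was 5.16-fold higher than the day 49/52 control (292 ± 44.4 against 56.7 ± 2.9; log2 2.37, SE 0.20, adjusted p = 0.0093) and kept its call against the day 13 control (log2 1.93, adjusted p = 0.029). The gene count against the day 49/52 control was 0 without replicate 2 of that control and 1178 without replicate 1, and 407 or 3297 without replicate 2 or 1 of rewatered root.

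The root controls of days 49/52 and day 13 were compared to see what changed in watered roots between the sampling days. They differed in 7701 genes, 3877 higher and 3824 lower on the later days. A fasciclin-like gene (Jcr4S06525.30) had 135 ± 40.1 CPM on the later days and 1 read at day 13 (0.00929 ± 0.0131), and the lipid binding gene Jcr4S00971.120 fell 213-fold to 6.3 ± 3.27. Ribosomal protein genes fell in 117 and rose in 2 of 145 (median -1.02, camera adjusted p = 4.7e-21, and adjusted p = 0.75 with an estimated correlation), class III peroxidases in 33 and 2 of 70 (-1.14, 2.7e-10, and 0.51), aquaporins in 17 and 3 of 31 (-1.07, 1.7e-07, and 0.54), cell division genes in 39 and 12 of 94 (-0.62, 4.6e-05, and 0.75) and wall loosening genes in 48 and 21 of 122 (-0.63, 0.009, and 0.51). WRKY factors rose in 18 and fell in 5 of 61 (0.66, 0.018, and adjusted p = 0.81 with an estimated correlation), NAC factors in 24 and 6 of 80 (0.47, 0.018, and 0.75) and HD-ZIP factors in 5 and 0 of 16 (0.62, 0.018, and 0.51). Photosystem genes had a median of -0.82 (0.015, and 0.81) and organelle-encoded genes -3.07 (0.0066, and 0.82). Secondary wall genes rose in 16 and fell in 13 of 49, with a median of -0.05 and a mean of 0.89. The gene count was 1620 or 3194 without replicate 2 or 1 of the later control and 5007 without replicate 2 of day 13.

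Leaf and root were compared for what they share and where they differ. In the day 13 controls 15230 of 25939 genes differed between the organs, 7535 higher in leaf. CYP86B1 (Jcr4S02060.30) had 18.7 ± 0.645 CPM in leaf and 1 read in root, and the B12D gene Jcr4S08627.40, with 0 reads in leaf, was at least 535-fold lower there. Under severe drought 2431 genes rose in both organs, where 1325.8 are expected if the calls were independent, and 2652 fell in both (expected 1538.2), out of 22218 genes tested in both. Another 787 rose in leaf and fell in root and 523 the reverse, and log2 fold changes correlated across genes with r = 0.342, where genes are not independent replicates. After rewatering 31 genes were higher in both organs (expected 14.7) and 170 lower (expected 61.2), and moderate drought shared 0 genes by edgeR and 77 by DESeq2. The severe overlap of 5083 genes was 3171 or 3185 without replicate 1 or 2 of the root control. The rewatered overlap was 79 or 0 without replicate 1 or 2 of the root control, 474 or 50 without replicate 1 or 2 of the leaf control, 23 or 16 without replicate 1 or 2 of rewatered leaf and 21 without replicate 2 of rewatered root.

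**Figure D5:**
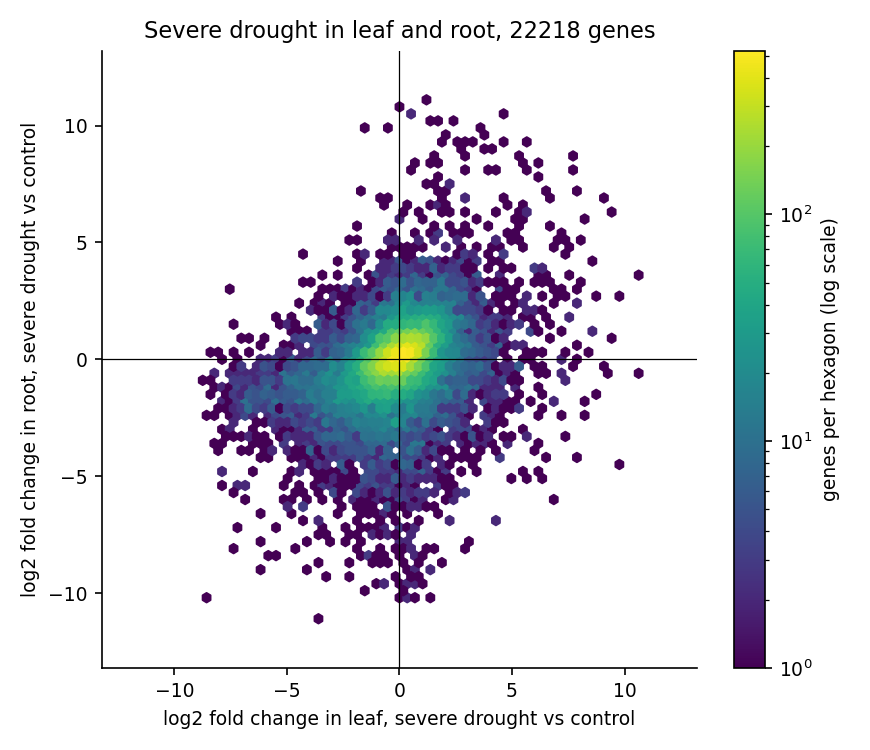
Log2 fold change of severe drought against control in leaf (horizontal axis) and in root (vertical axis) for 22218 genes tested in both, with colour giving the genes per hexagon on a log scale. The correlation across genes is 0.342, and 2431 genes rose and 2652 fell in both organs.

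The effect of a treatment was also tested for a difference between the organs, as the root effect minus the leaf effect. Under severe drought 9269 genes differed. Heat shock genes were higher in root in 51 of 74 and lower in 1 (median difference 3.48, camera adjusted p = 1.3e-19, and adjusted p = 0.079 with an estimated correlation), cell division genes in 59 and 2 of 97 (2.03, 2.6e-32, and adjusted p = 0.019 with an estimated correlation) and ribosomal protein genes in 131 and 5 of 147 (1.79, 7.8e-26, and 0.33). A comparison with the day 13 controls of both organs was added after seeing the data. It found 8242 genes, and the medians were 2.92 for heat shock genes (2e-21, and adjusted p = 0.076 with an estimated correlation), 1.30 for cell division (2e-21, and 0.066) and 0.36 for ribosomal proteins (0.068, and 0.93). The size of these differences thus depended on the control. Nitrate genes (-3.09, 0.00058, and adjusted p = 0.079 with an estimated correlation), gibberellin genes (-1.69, 1.2e-05, and 0.079) and WRKY factors (-1.54, 2.1e-05, and 0.30) were lower in root relative to leaf. For moderate drought 227 genes differed and for rewatering 2328. The moderate count was 76 or 1638 without replicate 2 or 1 of the root control, 52 without replicate 2 of the leaf control, 24 or 761 without replicate 1 or 2 of moderate root and 13 or 15 without replicate 1 or 2 of moderate leaf. The rewatered count was 731 or 1496 without replicate 2 or 1 of the root control, 955 without replicate 2 of the leaf control, 853 or 812 without replicate 1 or 2 of rewatered leaf and 1199 without replicate 2 of rewatered root.

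Genes that mark 1 organ were followed through the treatments as sets defined in other control libraries. In moderate drought the root libraries had root-enriched genes higher in 203 and lower in 53 of 3088 (median 0.55, camera adjusted p = 1.9e-07, and adjusted p = 0.072 with an estimated correlation) and leaf-enriched genes at -0.31 (1.4e-05, and 0.12). In moderate leaf the medians were 0.06 for leaf-enriched genes (adjusted p = 0.47) and -0.10 for root-enriched genes (0.018, and adjusted p = 0.55 with an estimated correlation), and -0.01 and -0.03 with sets defined at 4-fold. Root-enriched genes fell in severe root, 1571 lower and 117 higher of 2575 (median -2.03, camera adjusted p = 1.2e-28, and adjusted p = 0.00037 with an estimated correlation), and leaf-enriched genes had a median of 0.12 (0.027, and 0.45). In severe leaf, leaf-enriched genes fell in 600 and rose in 305 of 1401 (-0.43, 0.0048, and adjusted p = 0.34 with an estimated correlation) while root-enriched genes rose in 531 and fell in 283 of 1471 (0.58, 0.0048, and 0.32). In rewatered leaf both sets were below the control, leaf-enriched genes in 192 and root-enriched in 92 (-0.39, 2.7e-12, and adjusted p = 0.077 with an estimated correlation; -0.38, 0.00052, and 0.077). Rewatered root had leaf-enriched genes lower in 200 of 1026 (-0.76, 1e-09, and adjusted p = 0.072 with an estimated correlation) and root-enriched genes higher in 627 and lower in 332 of 2575 (0.46, 0.00023, and 0.072). These sets were defined in the day 13 controls, from which rewatered root differed in 10 genes and the day 49/52 root control in 7701. Their sizes depend on the controls, but most directions in root held (below). Moderate root sets were defined in the day 49/52 controls, which differed from moderate root in 1172 genes, so their direction stays open. The reverse choice, added after seeing the data, compared with the day 13 control the sets defined in the day 49/52 controls. There root-enriched genes were at -1.52 in severe root (1.5e-09, and adjusted p = 0.03 with an estimated correlation) and at 0.24 in rewatered root (0.0075, and 0.20). Leaf-enriched genes turned to -0.34 in severe root, without a call (0.19, and adjusted p = 0.60 with an estimated correlation), and were at -0.35 in rewatered root (8.4e-08, and 0.13).

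Within an organ, severe drought and rewatering were compared for shared genes, with both measured against the same 2 control libraries. In leaf 68 genes were higher in both (expected 49.4) and 385 lower in both (expected 259.8), while 208 and 42 went opposite ways. In root 322 were higher in both (expected 413.9) and 1215 lower in both (expected 539.4), while 205 and 867 went opposite ways. Simulated unchanged groups against a shared control, itself simulated, had a covariance of 0.077 in leaf and 0.142 in root, where 0.151 and 0.935 were observed. Their r was 0.502 and 0.501, where the observed r of 0.121 and 0.346 was lower. The observed covariance was thus above that of the simulated groups (highest 0.083 and 0.151). The real control libraries were not part of the simulation, so a spread of theirs beyond the fitted one is not covered. The leaf overlap was 37 or 54 without replicate 2 or 1 of rewatered leaf and 2248 or 118 without replicate 1 or 2 of the control. The root overlap was 0 or 527 without replicate 2 or 1 of the control and 173 without replicate 2 of rewatered root.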

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

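The tests of mature tissue, of exchanged labels, of a drought-like state of the later root controls, of the summed heat shock reads and of the spread of the leaf libraries, and the comparisons with the day 13 controls, were chosen only after the result was seen.

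The results here are differences between the effects of a treatment in both organs or at both stages, each found by a test of the difference itself in edgeR. The severe effect differed from the moderate effect in 8252 genes in leaf and 7541 in root, and the root effect differed from the leaf effect in 227 genes under moderate drought, 9269 under severe drought and 2328 after rewatering. The root count of 7541 was 4293 or 4634 without replicate 2 or 1 of the day 49/52 root control, 4910 without replicate 1 of severe root and 4952 without replicate 1 of moderate root. The moderate count of 227 was 76 or 1638 without replicate 2 or 1 of the day 13 root control, 24 or 761 without replicate 1 or 2 of moderate root, 52 without replicate 2 of the day 13 leaf control and 13 or 15 without replicate 1 or 2 of moderate leaf. The rewatered count of 2328 was 731 or 1496 without replicate 2 or 1 of the day 49/52 root control, 1199 without replicate 2 of rewatered root, 853 or 812 without replicate 1 or 2 of rewatered leaf and 955 without replicate 2 of the leaf control.

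Among the lists, camera with an estimated correlation called differences of effect for cell division in leaf between severe and moderate drought (median log2 difference -2.16) and between root and leaf under severe drought (2.03). With the day 13 controls, a comparison chosen after the result was seen, that difference was 1.30 and its call ended (adjusted p = 0.066). In root, the severe effect minus the moderate effect had a median of -1.03 for auxin response, -3.95 for gibberellin metabolism, 4.38 for heat shock proteins and -3.05 for secondary wall and lignin genes, a comparison not rerun with another control.

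Among single changed genes with an informative description and a mean log2 CPM of at least 3, the wall enzyme Jcr4S02117.30 had the largest positive difference between severe and moderate effects in leaf (log2 9.37) and the germin-like gene Jcr4S00461.10 the largest negative one (-9.07). In root these were the small heat shock gene Jcr4S02800.20 (15.09) and kiwellin Jcr4S01193.80 (-18.9). Kiwellin had 72.2 ± 14.3 CPM in the day 49/52 control and 0.0837 ± 0.118 in the day 13 control, so the size of its difference follows from the controls as well as from drought. Between root and leaf, the lipid binding gene Jcr4S00971.120 differed by -7.64 under moderate drought. Its call ended without replicate 2 of the day 13 leaf control (adjusted p = 0.053), without replicate 1 or 2 of moderate leaf (0.075 and 0.051) or without replicate 1 of moderate root (0.069). Under severe drought the small heat shock gene Jcr4S07181.20 differed by 11.37 and the nucleoid DNA-binding gene Jcr4S01213.30 by -12.66, the latter with severe leaf libraries far apart at 16 ± 17.7 CPM. With the day 13 controls these were 8.61 and -7.28. After rewatering the ceramidase gene Jcr4S01519.30 differed by -6.48, and its call ended without replicate 2 of the leaf control (adjusted p = 0.059) and against the day 13 controls (-1.04, adjusted p = 0.70).

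A first pattern is the distance between watered roots of day 13 and of days 49/52, where 7701 genes changed against 119 in leaf. The root count moved without single libraries (above). Library depth is argued against, since 7586 genes changed after every root library was thinned to the shallowest total. A state of the later controls like moderate drought stays open. The day 49/52 control minus rewatered root and moderate minus day 13 control share no library. They correlated across genes with r = 0.487 (0.341 to 0.553 leaving out each library). Exchanged labels with incomplete recovery could give this too. LEA genes held 0.173% and 0.166% of reads in the later controls, as at day 13 (0.183% and 0.168%). Moderate drought had 0.404% and 0.294%. More mature tissue in the tips stays open. Secondary wall (-0.05, replicate SD 0.24), suberin (0.09, SD 0.28) and root hair (-0.34, SD 0.52) medians lay within their SD. The cell division median (-0.62, SD 0.15) and the secondary wall mean (above) lay beyond it. Exchanged labels of rewatered and later control roots stay open too. Rewatered root and day 13 control differed in 10 genes (5126 at unadjusted p under 0.05, 4348 between leaf controls), as an exchange could give. Leaf and root rewatering effects had r = 0.164, where an exchange gives a negative r if organs recover alike. Plant age, named in the design, stays open and was not tested.

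A second pattern is the rise of heat shock proteins in severely droughted root. A shift of scaling by a few abundant genes was not tested, since it moves the list median and that of all genes alike. Their gap was at least 1.63 with every other method. Reads shared between near-identical small heat shock genes are argued against for the list as a whole, because sharing within the list leaves its sum unchanged and that sum was 6.26 times the control's share of reads. For the number of genes called the question stays open: 25 of 42 genes not described as small rose, which met the bound set beforehand against sharing, but after the result was seen that bound was judged wrong, because 26 of the 42 were classed as stating no size (19 of them higher) and may be small, apart from Jcr4S16636.10, described as protein 105 and not called, while of 16 with a stated larger size 6 rose. Severe drought itself is a candidate explanation for the rise of the list as a whole, as a hypothesis found and tested on the same data.

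A further pattern is that moderate drought changed 1 gene in leaf and 682 in root by edgeR, a difference tested by the 227 genes whose effect differed between the organs. A larger spread between leaf libraries is argued against, since the median SE in leaf was 0.895 times that in root over 22218 genes. Lower depth of the leaf libraries is argued against too, since 692 genes changed in root after thinning to the shallowest leaf total. The root count was 2 without replicate 2 of the day 13 control, 4379 without its replicate 1, and 19 or 1078 without replicate 1 or 2 of moderate root, and the leaf count was 51 without replicate 2 of its control, 19 without replicate 1 and 4 without either moderate library. The pattern thus rests on single libraries, and a stronger response of roots stays open with no biological explanation tested.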

How the results depend on the processing

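The comparisons with the day 13 control and with the list patterns as first spelled were chosen after seeing the data. Counts of changed genes under severe drought kept within 1.5 times of the edgeR count in every setting that used all libraries (root severe drought fell further when a library was left out), as did those of rewatering against severe drought. Those of moderate drought, of rewatering against the control and of the leaf controls moved. With 2 libraries per group, leaving out 1 leaves an arm with a single library, which is assumed to vary like the other groups. The spread is pooled over the groups of an organ. The day 49/52 controls carry a joint label of days and serve severe drought and rewatering alike. The way reads of near-identical genes were counted is not given in the sources used here. The cause was not tested for any value below unless a clause gives it. RLE size factors moved no count beyond 1.5 times.

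DESeq2 called 280 genes in moderate leaf, 2748 in rewatered leaf, 1540 between leaf controls of days 13 and 0, 1543 between those of days 49/52 and 13, 3148 in moderate root, 1206 and 3813 for the organ difference under moderate drought and rewatering, and overlaps of 77 (moderate), 584 (rewatered) and 1035 (leaf severe with rewatered). Its falsely called genes in simulated copies were 38 in moderate leaf and 67 in moderate root, against 7 and 3 by edgeR. Without a filter on low counts the same results, in that order, were 689, 3558, 2128, 1965, 4311, 2170, 4054, 220, 789 and 1452, with 6809 genes in rewatered root, 2752 shared by severe and rewatered root, and 12 lists called in moderate root. The stricter filter gave 253 genes between leaf controls of days 49/52 and 13 and 963 shared by severe and rewatered root. A replicate block gave 3 genes in moderate leaf, 18 between leaf controls of days 49/52 and 13 and 128 in the rewatered overlap. A single fit over all libraries gave 0 genes in moderate leaf, 269 and 71 between the leaf controls of days 13 and 0 and of days 49/52 and 13, 2824 in moderate root and 2335 shared by severe and rewatered root.

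On the deposited RPKM with limma, plus 1, plus 0.1 and plus 1 without a filter, moderate leaf had 0, 0 and 0 genes (2055, 2024 and 2515 at an unadjusted p under 0.05, and 1553 in the single fit), rewatered leaf 565, 510 and 387, the organ difference 832, 540 and 784 under moderate drought and 4242, 3875 and 4031 after rewatering, the rewatered overlap 130, 115 and 72, and severe with rewatered leaf 293, 257 and 213. Leaf controls of days 13 and 0 differed in 234 genes at plus 0.1 and 148 without a filter, and those of days 49/52 and 13 in 44 without a filter. On these RPKM the median of all genes in severe root moved by 0.123, 0.167 and 0.126, and 57.2%, 55.8% and 57.2% of changed genes were higher in place of 43.2%. For rewatered against severe root the shift was -0.125, -0.179 and -0.125, and for the severe minus the moderate effect in root 0.190, 0.229 and 0.193. At plus 0.1 it was 0.121 between leaf and root and 0.117 for the organ difference under severe drought.

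Against the day 13 control, rewatered leaf had 2411 changed genes and rewatered root 10, with 1490 for the organ difference after rewatering, 0 in the rewatered overlap and 8 shared by severe and rewatered root. Medians that changed sign were those of ribosomal proteins in severe root (-0.10) and, in rewatered root, aquaporins (-0.55), wall loosening (-0.13), ribosomal proteins (-0.56) and organelle-encoded genes (-0.39). The named genes that changed sign were Jcr4S01152.10 in severe root (-0.45) and, in rewatered root, Jcr4S00971.120 (-1.33), Jcr4S01309.10 (-0.68), Jcr4S06525.30 (5.76), Jcr4S06525.40 (0.49), Jcr4S01772.30 (4.50), Jcr4S02908.30 (0.34), Jcr4S01692.40 (-0.13), Jcr4S02850.20 (-0.13), Jcr4S01265.30 (0.99), Jcr4S01656.20 (-0.08), Jcr4S12402.20 (0.02), Jcr4S02318.30 (0.28), Jcr4S02315.40 (0.94), Jcr4S01793.30 (-0.22), Jcr4S03877.90 (-0.42), Jcr4S04216.20 (-0.56), Jcr4S00170.20 (-0.62) and Jcr4S02308.50 (0.54). These values follow another baseline by construction, with the same drought or rewatered libraries. In moderate leaf peroxidases were at 0.04 with the stricter filter, and without replicate 2 of the day 13 control heat shock genes were at 0.35, Jcr4S22396.10 at -0.01 and Jcr4S00096.100 at 0.77, against -0.51, 0.11 and -3.85 without replicate 1.

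With an estimated correlation camera called 0, 1 and 0 lists in moderate, severe and rewatered leaf and 0, 3 and 0 in root, and fry called 1 and 22 in moderate and severe leaf. Calls of organ-enriched sets were lost with an estimated correlation at medians of -0.10 (root-enriched, moderate leaf), -0.43 and 0.58 (severe leaf), -0.39 and -0.38 (rewatered leaf), -0.31 and 0.55 (moderate root), 0.12 (leaf-enriched, severe root), -0.76 and 0.46 (rewatered root), and with fry at -0.10 and 0.12. With 4-fold sets the medians in moderate leaf were -0.01 (leaf-enriched) and -0.03 (root-enriched). The lists as first spelled gave numbers of called lists within 1.5 times in all 6 main comparisons.

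Leaving out each library in turn gave, from lowest to highest, 4 to 51 genes in moderate leaf, 10869 to 12892 in severe leaf, 53 to 4582 in rewatered leaf, 10504 to 13116 for rewatered against severe leaf, 5854 to 9127 for severe minus moderate leaf, 2 to 413 and 2 to 820 between the earlier and the later leaf controls, 2 to 4379 in moderate root, 6781 to 7473 in severe root, 0 to 3297 in rewatered root, 8957 to 10281 for rewatered against severe root, 4293 to 8825 for severe minus moderate root and 1620 to 9269 between root controls. Between the organs it gave 12653 to 14965 in controls, and for the organ difference 13 to 1638 (moderate), 6972 to 9103 (severe) and 731 to 3331 (rewatered). Overlaps ran from 0 to 5 (moderate), 3171 to 4755 (severe), 0 to 474 (rewatered), 37 to 2248 (severe with rewatered leaf) and 0 to 1199 (the same in root). Called lists ran from 4 to 10, 5 to 9 and 11 to 15 in moderate, severe and rewatered leaf and from 7 to 8, 16 to 18 and 4 to 6 in root. Over all named genes and left-out libraries, 855 values kept direction and side of the threshold, 264 lost the call, 15 gained it and 2 changed sign. With DESeq2 244 kept both and 30 gained a call, and with RLE size factors 272 kept both and 2 lost the call.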

Other observations

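Genes of leaves in watered plants moved between day 0 and day 13 in groups not described so far. Curcin genes rose in 2 of 4, and in 3 adjusted over the list alone (median log2 fold change 1.28, camera adjusted p = 0.00033, and adjusted p = 0.38 with an estimated correlation). Chlorophyll breakdown genes rose in 2 of 11, and in 5 with 1 lower adjusted over the list alone (0.64, 0.0017, and adjusted p = 0.49 with an estimated correlation), and carbon fixation genes fell in 2 of 11, and in 6 with 1 higher adjusted over the list alone (-0.59, 0.00033, and adjusted p = 0.40 with an estimated correlation). Class III peroxidases rose in 2 of 49, and in 11 with 1 lower adjusted over the list alone (0.39, 0.00033, and adjusted p = 0.29 with an estimated correlation).

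In leaf, rewatering against severe drought lowered genes of several stress families. WRKY factors fell in 29 and rose in 7 of 52 (median -1.37, camera adjusted p = 0.0064, and adjusted p = 0.58 with an estimated correlation), NAC factors in 31 and 13 of 71 (-0.39, 0.044, and 0.58), glutathione transferases in 17 and 6 of 31 (-1.22, 0.0074, and 0.59), LEA and dehydrin genes in 9 and 3 of 16 (-0.83, 0.044, and 0.28) and chlorophyll breakdown genes in 8 and 1 of 11 (-1.83, 0.0049, and 0.46). In root the same comparison had ABA breakdown genes lower in 4 and higher in 1 of 6 (-5.99, 0.006, and adjusted p = 0.11 with an estimated correlation). The gene described as mta sah (Jcr4S09196.10) was the most abundant gene of all severe libraries, with 2.89% and 3.98% of reads in root and 1.65% and 1.79% in leaf.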
